A study of Mus musculus with 33 samples.

How the data were processed

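RNA was sequenced from mouse tongues at E13.5, P0 and P20 and from sorted costal chondrocytes at E18.5, in wild type mice and in mice that express the imprinted gene Zac1 (Plagl1) from both alleles. The labels' protocols describe 3 biological replicates per genotype and stage for the tongues, and 6 biallelic and 5 wild type replicates for the chondrocytes. Tongue libraries were strand-specific (dUTP method) and made after removal of ribosomal RNA, per the labels' protocols. Chondrocyte libraries were SMART-seq2 libraries of polyadenylated RNA from small pools of sorted cells, per the labels' protocols. The sorted population carried both Cd24a and Cd200 on its surface, which the labels give as the gate for prehypertrophic chondrocytes. Litter, sex and preparation date are not given in the sources used here, and Y-linked transcripts were examined in the chondrocytes.

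The authors deposited 4 tables of log2 values, each log2 RPM per gene, where RPM are reads scaled to the read total of the library, with no correction for gene length. Per the submitters' processing notes, Trim Galore 0.4.2 was used, with TopHat2 2.1.0 for the tongues and HISAT2 for the chondrocytes, on the genome build GRCm38. The read counter and its strand setting are not given in the sources used here, so overlapping and antisense genes cannot be told apart with certainty. Each tongue table held 27825 genes, all on the numbered chromosomes, and the chondrocyte table held 25965. The smallest value of each library equalled 0.9 reads, which stands for a gene with 0 reads. Within 0.05 of a read, 100% of values below 1000 reads came out as whole reads in every library, so the denominator behind each RPM value was recovered. It ranged from 36832717 to 92249098 reads in the tongues and from 2938462 to 15689559 in the chondrocytes. Listed genes held 32.13% to 37.64% of that denominator in the tongues and 55.45% to 65.79% in the chondrocytes. For 4 chondrocyte animals, all of them biallelic, the labels list 2 libraries each, while the table holds 1 column per animal. No wild type animal has a repeat library, so an effect of combining libraries cannot be told apart from genotype. How both libraries became 1 column is not given in the sources used here. The whole reads in these 4 columns argue against a mean of 2 log2 values per gene. Pooled reads, or the reads of 1 library alone, stay open. Each animal counted once. The averaging of repeat libraries that had been planned was therefore not needed. In total 33 labelled samples correspond to 29 columns.

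Genes at 1 RPM or more in at least 3 of the 6 libraries of a tongue table, or in at least 5 of the 11 animals of the chondrocyte table, were tested with limma 3.58.1 in R 4.3.3 (linear model, moderated test with a mean-variance trend). No value was added before the logarithm beyond the 0.9 reads set by the authors, which can understate the change of genes near that floor. A gene with 0 reads also gets a lower value in a deeper library, and the biallelic chondrocyte libraries were mostly deeper, so genes near the floor appear lower there. Without the filter 4418 of the 4940 chondrocyte genes at an unadjusted p under 0.05 were lower. The contrast was biallelic minus wild type within each table, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Differences of the genotype effect between stages were tested in 1 fit of all 18 tongue libraries over the 10929 genes that passed the filter in all 3 tables. The genotype effect averaged over the 3 stages was added to that fit after the data were examined. Library pairs were compared for duplicates, and every pair differed by far more than sampling noise (chi-square per degree of freedom of at least 6.93).

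The comparisons, the settings to be varied, 26 gene lists and the rule for the genes named were fixed before the data were examined. The rule takes Plagl1 in each table, up to 12 rising and 12 falling genes past the threshold whose groups do not overlap, and the 10 genes of smallest p in a table with fewer than 5 genes past it. From each list described it takes the members past the threshold when adjusted over the list alone, or else the 2 of smallest p. That adjustment does not allow for the number of lists, so some such members can arise by chance. It also takes genes past the threshold in the contrasts between stages or in several tables. Some genes that this rule takes are not reported here. Which lists to describe in each table was chosen after the results were seen. Genes named outside the rule (those near Plagl1, markers of the sorted cells, marker genes of other cells, and genes of the averaged effect) were chosen after their values were seen. Lists were tested with fry, which asks whether the genes of a list move on balance one way, or in either direction (mixed). They were also tested with camera, which compares a list with the other genes, with a preset correlation and with an estimated one.

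The limma step was tested on simulated data drawn from the means and library sizes of each table, with 200 changed genes. Fry and camera were tested on such data with a single moved list and 100 unmoved lists per table. The moved list had an unadjusted p of at most 9.39e-06 with fry and 3.21e-35 with camera. Of the unmoved lists, fry gave 1 to 8 per table an unadjusted p under 0.05 and camera 0 to 5. Noise was drawn for each gene on its own, unlike in the real libraries, so camera's preset correlation was not put to the test. Many changed genes also ease the adjusted threshold. The simulated shares need not hold for the real tables, where Plagl1, 2.29-fold higher at E13.5, was not called at that stage. For the genotype contrast, 58% of genes changed 2-fold and 84% of genes changed 4-fold were called at E13.5, 62% and 93% at P0, 58% and 92% at P20, and 24% and 60% in the chondrocytes. For the averaged effect the shares were 94% and 95%, and for the contrast of P20 and P0 they were 51% and 89%. Unchanged genes called beside them numbered 6 to 9 for the genotype contrasts, 11 for the contrast of P20 and P0 and 18 for the averaged effect, more than 5% of the calls in each except P20. Alternatives tried were median centring, quantile normalization, log2(RPM + 1), no filter, a filter at 5 RPM, no trend, a robust trend, array weights, voom on the recovered whole reads, the replicate number as a block, a Y-linked covariate in the chondrocytes and leaving out each replicate. Single values were tested by exact permutation, and overlaps and positions by Fisher's exact test. Positions are those of the deposited tables. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for tables and plots.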

Results

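The data set comprised 18 tongue libraries, 3 wild type and 3 biallelic at each of E13.5, P0 and P20, and libraries of costal chondrocytes from 6 biallelic and 5 wild type animals at E18.5. Plagl1 (also called Zac1) encodes a zinc finger transcription factor and is imprinted, with expression from the paternal allele alone in most tissues. The series asked which genes respond when Plagl1 is expressed from both alleles, in the growing tongue and in cartilage. Read totals behind the RPM values were 36832717 to 52425994 at E13.5, 48336734 to 92249098 at P0 and 45370175 to 58251242 at P20. Chondrocyte libraries were shallower, at 7221013 to 15689559 reads in the biallelic and 2938462 to 7887305 in the wild type animals. A count of 3 reads corresponded to 0.0325 to 0.0814 RPM in the tongues and to 0.1912 to 1.0209 RPM in the chondrocytes, counting error only.

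Plagl1 itself was higher in the biallelic than in the wild type libraries in every table. The gene (ENSMUSG00000019817) lies on chromosome 10 of GRCm38, from 13090691 to 13131694. At E13.5 it reached 203.2 ± 62.9 RPM in the biallelic tongues and 87.6 ± 19.7 RPM in the wild type tongues (SD, n = 3 each). At P0 the levels were 473.0 ± 37.8 and 231.2 ± 10.97 RPM (SD, n = 3 each), a 2.04-fold difference, and at P20 they were 64.9 ± 13.2 and 26.2 ± 3.83 RPM (SD, n = 3 each). In the chondrocytes Plagl1 was at 27.9 ± 11.6 RPM in the biallelic animals (SD, n = 6) and 8.94 ± 4.63 RPM in the wild type animals (SD, n = 5). The log2 fold changes were 1.20 (SE 0.23) at E13.5, 1.03 (SE 0.10) at P0, 1.30 (SE 0.18) at P20 and 1.74 (SE 0.38) in the chondrocytes. Every biallelic value lay above every wild type value within each table, and chance separates the groups, in 1 direction or the other, for 10% of genes with 3 against 3 libraries and for 0.43% with 6 against 5. Across genes, limma's adjusted p passed the threshold at P0 (0.0469) and not at E13.5 (0.992), at P20 (1) or in the chondrocytes (0.423). For Plagl1 as a single gene, permuting genotypes within the 3 tongue stages gave an exact two-sided p of 0.00025, the smallest that the 8000 arrangements allow. The chondrocyte values gave an exact two-sided p of 0.00216, also the smallest possible.

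**Figure D1:**
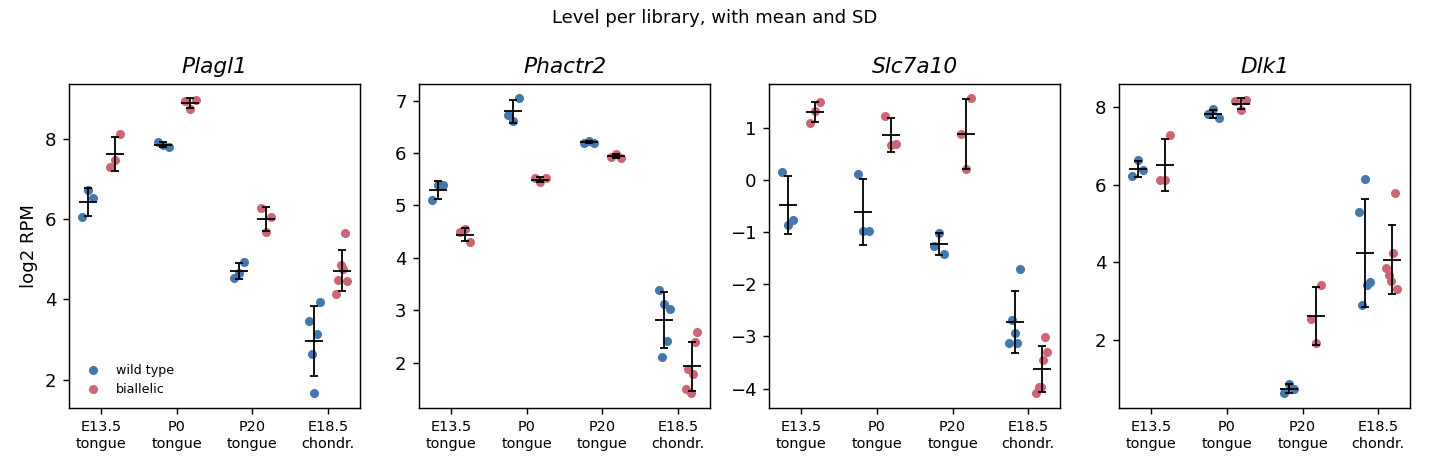
Level (log2 RPM) of Plagl1, Phactr2, Slc7a10 and Dlk1 in each library by table, with wild type in blue, biallelic in red, and the mean and SD in black. Plagl1 was higher and Phactr2 lower in all 3 biallelic libraries than in all 3 wild type libraries at each tongue stage. The 4 tables were deposited separately and may have been normalized separately, so levels are compared within a table. Slc7a10 had at most 1 read in any chondrocyte animal, so its values there show the floor and not a level.

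In the E13.5 tongue the smallest p-values belonged to Phactr2, Pappa2 and Plagl1. Phactr2, a regulator of protein phosphatase and actin whose gene lies close to Plagl1, was at 21.9 ± 1.95 RPM in the biallelic and 39.4 ± 4.47 RPM in the wild type libraries (SD, n = 3 each). Pappa2, a protease that frees insulin-like growth factors from their binding proteins, differed by a log2 fold change of -1.74 (SE 0.30). Slc7a10, an amino acid transporter, differed by 1.79 (SE 0.40). Also among the 10 genes of smallest p were Galnt10 (-0.57), Tbk1 (-0.57), A430107O13Rik (-0.66), Gm4294 (0.65) and Gm11808 (0.55). None of these passed the threshold over all genes. Limma called 0 of 11869 genes, with 386 at an unadjusted p under 0.05 where chance gives 593, and voom on the whole reads also called 0. Of those 386 genes 293 were lower and 93 higher in the biallelic tongues, against 130 lower and 200 higher after median centring. Groups did not overlap for 10.1% of genes, where chance gives 10%.

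Gene lists at E13.5 were marked by 1 library. All 17 tested genes of the hypoxia and glycolysis list had higher means in the biallelic tongues, with a median log2 fold change of 0.71, including Aldoa (0.82) and the glucose transporter Slc2a1 (1.24). Biallelic replicate 3 had a list mean of 6.20 log2 RPM, against 3.91 to 4.03 in the other 5 libraries, and without it 11 of the 17 genes were higher, with a median of 0.06. Camera with a preset correlation called this list (adjusted p = 3.28e-10), and the adjusted p = 0.770 with an estimated correlation. It also called the imprinted, extracellular matrix and insulin and IGF signalling lists (camera adjusted p = 0.0155 each). With an estimated correlation their adjusted p was 0.770 too. In the insulin and IGF signalling list Pappa2 fell when adjusted over the list alone and 25 of the 26 tested members did not pass. No member passed among 41 imprinted genes (Magel2 0.39, Rtl1 0.56), 42 extracellular matrix genes (Fbln5 -0.48, Lox 0.91) or 15 reported Plagl1 targets (Dcn 0.36, Tcf4 -0.22). The same replicate moved these medians too. They were 0.02, 0.10 and -0.02 with it and -0.16, -0.14 and -0.22 without it. The erythroid list mean was 4.96 in biallelic replicate 3 and 2.76 to 4.15 in the others, and the endothelial list mean was 2.97 against 1.43 to 2.30. With fry no list passed at E13.5 (smallest adjusted p = 0.985).

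At P0 Plagl1 rose and the nearby gene Phactr2 fell in the biallelic tongue, and these were the 2 genes called. Phactr2 was at 45.0 ± 1.31 RPM in the biallelic and 111.9 ± 17.7 RPM in the wild type libraries (SD, n = 3 each), a log2 fold change of -1.30 (SE 0.12, limma adjusted p = 0.0469). The next genes did not pass the threshold. They were Trpm5, an ion channel of taste cells (0.80), Pi15 (-1.16), the fucosidase gene Fuca2 (-0.85), the cartilage collagen gene Col9a2 (1.04), Ppp1r3c, a glycogen-targeting phosphatase subunit (-0.86), the lysosomal sulfatase gene Arsb (0.50), Clec3b (-0.84) and the immune receptor gene Ctla4 (1.12). Limma called 2 of 12489 genes, with 412 at an unadjusted p under 0.05 where chance gives 624. Voom on the whole reads called 0, with Phactr2 at an adjusted p of 0.0534, and median centring or quantile normalization left Phactr2 as the 1 gene called. No filter, no trend, a robust trend and the replicate block each called 0 as well. The count ranged from 0 to 4 when single replicates were left out, and Phactr2 stayed between -1.39 and -1.18. It was 2 without biallelic replicate 1 (neither of them Plagl1 or Phactr2), 4 without wild type replicate 3 (Eef1a2, Myh1, Myh2 and Phactr2, all lower) and 0 without any other library. Wild type replicate 2 and biallelic replicate 1 lay at 29.0 and 28.0 on the first principal component and the other 4 libraries between -20.5 and -7.1.

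Among the lists at P0, 29 of 35 tested skeletal muscle contractile genes had lower means in the biallelic tongue, with a median log2 fold change of -0.18 and no member past the threshold. The fast myosin heavy chain gene Myh1 differed by -1.91, with an SD of 0.93 among the wild type libraries, and the slow troponin gene Tnni1 by 0.50. Camera with a preset correlation called the list (adjusted p = 6.67e-09), and the adjusted p = 0.509 with an estimated correlation. All 10 tested Hedgehog targets had higher means (median 0.19, Foxf2 0.33, Foxd1 0.44), with a camera adjusted p = 0.00110 and an adjusted p = 0.362 with an estimated correlation. Of 24 myogenic progenitor genes 16 were higher (median 0.04), among them Pax3 (0.62) and Megf10 (0.37), with a camera adjusted p = 0.0373 and an adjusted p = 0.362 with an estimated correlation. The preset correlation also called 5 lists with mostly lower members, namely macrophage and leukocyte (13 of 15 lower), immediate early and stress (13 of 16), nerve and glia (9 of 10), hypoxia and glycolysis (12 of 16) and adipocyte (10 of 16), and the estimated correlation called none of them. Adjusted over the list alone, Trpm5 rose among 4 tested salivary gland and taste genes and Col9a2 rose among 9 tested growth plate chondrocyte genes. The salivary gland and taste list passed fry's mixed test (adjusted p = 0.00167) and not its directional test (adjusted p = 0.308). Of its 23 members 4 were tested, 2 higher and 2 lower. Trpm5, one of them, had very small SDs (0.0445 biallelic and 0.0109 wild type, log2 RPM) and a limma adjusted p of 0.601 over all genes. Whether the list passes without Trpm5 was not tested. No member passed among 42 imprinted genes (33 higher, median 0.09, Dlk1 0.26, Magel2 0.30) or 16 reported Plagl1 targets (12 higher, median 0.11, Grb10 0.22). No list passed fry's directional test at P0 (smallest adjusted p = 0.182).

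At P20 the genes of smallest p after Plagl1 included Slc7a10 and Dlk1, an imprinted inhibitor of adipocyte differentiation. Slc7a10 was at 1.99 ± 0.91 RPM in the biallelic and 0.43 ± 0.06 RPM in the wild type tongues, and Dlk1 was at 6.75 ± 3.51 and 1.68 ± 0.14 RPM (SD, n = 3 each). Their log2 fold changes were 2.12 (SE 0.36) and 1.88 (SE 0.34). Others were the matricellular gene Cyr61 (0.71), the surface antigen gene Thy1 (-0.75), the cholesterol transporter gene Abca1 (0.58), Vsig2 (0.59), Aldh1l2 (-0.50) and the microRNA gene mmu-mir-689-2 (-1.07). None passed the threshold over all genes. Limma called 0 of 12693 genes, with 286 at an unadjusted p under 0.05 where chance gives 635, and voom called 0.

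Dlk1 rose at P20 when adjusted over the list alone, both among 34 imprinted genes (24 higher, median 0.13) and among 16 reported Plagl1 targets (13 higher, median 0.18). On the same terms Pnpla2, the lipase that begins triglyceride breakdown, rose in the adipocyte list of 16 genes (0.62, list median 0.39). Thy1 likewise fell in the perichondrial fibroblast list, where 14 of 16 genes were lower (median -0.22). Dlk1, Pnpla2 and Thy1 did not pass over all genes, and adjustment over the list alone does not allow for the number of lists. Of 15 endothelial genes 14 were higher, with a median of 0.35 and none past the threshold (Sox17 0.42, Cldn5 0.97). Among 21 myogenic progenitor genes 16 were higher (median 0.12, Myod1 0.58, Spry1 0.18), also with none past it. Camera with a preset correlation called 13 lists, these 6 among them. Of the other 7, members were mostly lower in the extracellular matrix (31 of 43), macrophage and leukocyte (14 of 17), cell cycle (23 of 29), osteoblast (6 of 6) and Wnt target (9 of 10) lists and mostly higher in the immediate early and stress (14 of 18) and hypoxia and glycolysis (12 of 17) lists. With an estimated correlation the adjusted p = 0.311 for the adipocyte list, the adjusted p = 0.517 for the endothelial list and the Plagl1 targets, and the adjusted p = 0.544 for the imprinted, fibroblast and myogenic progenitor lists, and no list was called. Fry called no list (smallest adjusted p = 0.210). Biallelic replicate 3 stood apart on the first principal component, at -39.8 against -10.1 to 22.4 in the other libraries. Without it the medians of the 6 lists first named were 0.03 for the imprinted genes, 0.05 for the Plagl1 targets, 0.12 for the adipocyte, 0.13 for the endothelial, -0.37 for the fibroblast and -0.01 for the myogenic progenitor list. Of the other 7, the cell cycle and hypoxia lists turned (14 of 29 and 10 of 17 lower, medians 0.02 and -0.05), the Wnt target median was -0.06, and the matrix (39 of 43 lower), macrophage (17 of 17 lower), osteoblast (5 of 6 lower) and stress (17 of 18 higher) lists kept their direction.

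Comparing stages, the genotype effect on Phactr2 was smaller at P20 than at P0. The difference was 1.04 on the log2 scale (SE 0.16) and missed the threshold in limma (adjusted p = 0.0694), and it passed with median centring, with a filter at 5 RPM or without wild type replicate 2 of P0. Limma called 0 of 10929 genes in each of the 3 contrasts between stages, with 583 at an unadjusted p under 0.05 for P0 minus E13.5, 155 for P20 minus P0 and 388 for P20 minus E13.5. Averaged over the 3 stages, a test chosen after the data were examined, 4 genes were called. Phactr2 fell by 0.80 (adjusted p = 8.98e-06), and rises were called for Plagl1 (1.18, adjusted p = 8.97e-05), Slc7a10 (1.79, adjusted p = 0.000797) and Ctla4 (0.76, adjusted p = 0.0370). With a filter at 5 RPM 2 genes were called, Phactr2 and Plagl1, since the other 2 lie below that level. Under log2(RPM + 1) the value of Slc7a10 was 0.92 in place of 1.79, still called. Ctla4 lost its call under log2(RPM + 1), where its value was 0.45, with the replicate block and when most single libraries were left out.

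Plagl1 and Phactr2, the 2 genes called at P0, both lie in a window of 5 Mb to either side of Plagl1 on chromosome 10 that holds 29 tested genes. Phactr2 starts at 13207717 and ends at 13474396, 76.0 kb beyond Plagl1 with Ltv1 between them, and Fuca2 (13499540 to 13519035) and Pex3 (13523842 to 13553142) follow it. Leaving out Plagl1, 3 genes of that window had an unadjusted p under 0.01 at P0 (Phactr2, Fuca2 and Pex3, where 0.12 were expected), 2 at E13.5 (Ltv1 and Phactr2, 0.09 expected), and 0 at P20 and in the chondrocytes. One-sided Fisher's exact tests, with Plagl1 left out, gave 0.000245 at P0 and 0.00325 at E13.5. Over all of chromosome 10, again without Plagl1, 6 genes had such a p at E13.5 (1.97 expected) and 7 at P0 (2.79 expected). At P20 there were 6 (2.26 expected), all outside the window, and in the chondrocytes 12 (11.06 expected). The same Fisher's exact test gave 0.0126 at E13.5, 0.0204 at P0, 0.0242 at P20 and 0.428 in the chondrocytes. In the averaged effect the 7 tested genes within 1 Mb beyond Plagl1 all had negative values, from Ltv1 (-0.36), Phactr2 (-0.80), Fuca2 (-0.52) and Pex3 (-0.26) to Adat2 (-0.21), Aig1 (-0.12) and Hivep2 (-0.20), and of these Phactr2 passed the threshold. The 3 genes before Plagl1 were at 0.03 (Utrn), -0.02 (Stx11) and -0.17 (Sf3b5).

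**Figure D2:**
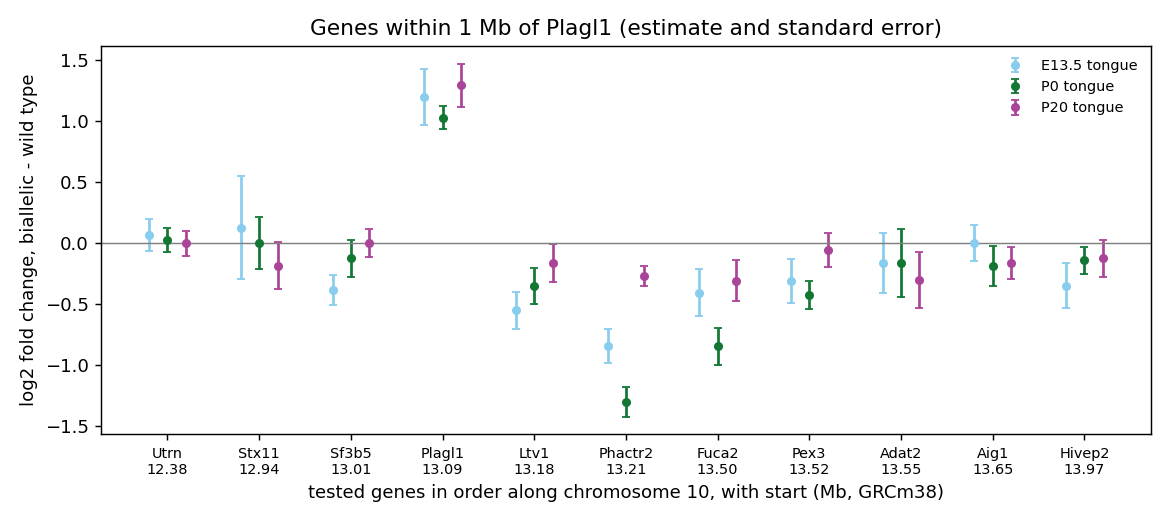
Log2 fold change (biallelic minus wild type, with its standard error) of the tested genes within 1 Mb of Plagl1, in order along chromosome 10, for the 3 tongue stages. Plagl1 is above 1 at each stage, and Phactr2, at -0.85, -1.30 and -0.27, is below 0 at each.

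In the costal chondrocytes Plagl1 was again higher, and most other genes of small p were lower in the biallelic animals. Among the 10 of smallest p were Alox5, the leukocyte enzyme that starts leukotriene synthesis (-2.51), Mmp9, a matrix metalloprotease of osteoclasts and leukocytes (-1.86), Cd55, a complement regulator (-2.25), and Psme3, a proteasome activator subunit (-1.99). The RNA-binding genes Hnrnpu (-1.50) and Pcbp1 (-1.12), and Rab5a (-1.07), Top2b (-0.83) and Zfp106 (-0.75), completed them. All kept their direction over the alternatives, while some shrank, with the weakest values at -0.54 for Pcbp1, -1.49 for Alox5, -1.33 for Cd55 and -1.20 for Psme3. None passed the threshold. Limma called 0 of 11127 genes, with 1298 at an unadjusted p under 0.05 where chance gives 556, and voom called 0. Of the 1298 genes 858 were lower and 440 higher, against 526 lower and 789 higher after median centring, since the median log2 fold change over all tested genes was -0.11. The groups did not overlap for 97 genes (0.9%, where chance gives 0.43%). Wild type animals 7, 8 and 9 stood apart on the first principal component (64.3, 79.8 and 89.8), with the other 8 animals between -52.2 and 17.2. Without these 3 animals 0 genes were called and 387 had an unadjusted p under 0.05. The Y-linked gene Ddx3y was detected in 3 of 6 biallelic and 1 of 5 wild type animals, so the sexes were not balanced, and with a Y-linked covariate 0 genes were called and 1045 had an unadjusted p under 0.05.

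Chondrocyte genes were present in these libraries beside abundant leukocyte transcripts. Col2a1, the main collagen of cartilage, was at 526.7 ± 169.6 RPM in the biallelic (SD, n = 6) and 289.4 ± 102.7 RPM in the wild type animals (SD, n = 5). Acan, also a growth plate gene, differed the other way, at 12.7 ± 6.62 RPM (SD, n = 6) and 19.1 ± 14.5 RPM (SD, n = 5). The sort markers were detected, with Cd24a at 48.7 ± 5.71 and Cd200 at 15.5 ± 6.29 RPM in the biallelic animals (SD, n = 6). In the wild type animals they were at 40.7 ± 9.22 and 12.55 ± 4.75 RPM (SD, n = 5). In the unsorted tongues, whose libraries were of another type, group means ranged from 29.0 to 96.2 RPM for Cd24a and from 2.48 to 13.9 RPM for Cd200. Detection of both markers thus does not show that the gate enriched the intended cells. Csf1r, the receptor of macrophage growth factor, was at 655.7 ± 109.0 and 469.9 ± 122.6 RPM, and Lyz2 at 949.7 ± 293.9 and 921.1 ± 221.7 RPM, in the biallelic (n = 6) and wild type (n = 5) animals (SD). The median level of the 22 tested macrophage and leukocyte genes was 7.03 log2 RPM. It was 4.80 for the 13 tested of 25 prehypertrophic and hypertrophic genes and 3.36 for 18 tested growth plate genes. The hypertrophic gene Col10a1 was at 0.30 ± 0.21 and 0.33 ± 0.19 RPM (SD, n = 6 and 5) and did not pass the filter. Nor did Ihh, a member of the prehypertrophic and hypertrophic list, at 0.32 ± 0.59 and 0.17 ± 0.08 RPM (SD, n = 6 and 5).

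Growth plate genes had higher means in the biallelic chondrocytes for 14 of 18 members, with a median log2 fold change of 0.44 and none past the threshold (Col2a1 0.87, Lect1 2.37, the latter 1.36 without wild type animal 8). Camera with a preset correlation called the list (adjusted p = 0.00295), and the adjusted p = 0.854 with an estimated correlation. Of the prehypertrophic and hypertrophic genes 10 of 13 were higher (median 0.25, Vegfa -1.07, Phospho1 0.91). Cell cycle genes were lower for 26 of 29 members (median -0.70, Ccnb1 -1.53, Mcm6 -0.99), and perichondrial fibroblast genes for 9 of 11 (median -0.75, Mfap5 -1.77, Prrx1 -1.25). The 3 wild type animals 7, 8 and 9 had high means of the cell cycle list (3.66, 2.94 and 4.14 log2 RPM) and of the fibroblast list (3.92, 3.36 and 5.26). Biallelic animal 5 was similar at 3.48 and 5.10, and the other 7 animals reached at most 2.40 and 3.04. Without animals 7, 8 and 9 the medians were 0.09 for cell cycle, 0.12 for fibroblast, 0.49 for growth plate and -0.09 for prehypertrophic genes. Mfap5 and Prrx1 then turned to 0.45 and 0.12. Over the alternatives Ccnb1 ranged from -1.98 to -0.22, Mcm6 from -1.25 to -0.07 and Vegfa from -1.31 to -0.17.

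In the macrophage and leukocyte list S100a8, a calcium-binding protein of neutrophils, fell when adjusted over the list alone (-1.82), and 14 of 22 members had higher means (median 0.02). S100a8 was at 89.1 ± 26.5 RPM in the biallelic animals (SD, n = 6) and 402.0 ± 277.7 RPM in the wild type animals (SD, n = 5), and without wild type animals 7, 8 and 9 its log2 fold change was -0.39. Among 13 transcripts of the mitochondrial genome 5 rose when adjusted over the list alone, namely mt-Co3 (4.86), mt-Co2 (4.92), mt-Nd4l (3.43), mt-Atp8 (4.36) and mt-Atp6 (4.67), while 6 had lower means (1 of 13 without wild type animals 7, 8 and 9). The list mean was 6.89, 6.87 and 7.39 log2 RPM in biallelic animals 1, 3 and 4 and 3.72 to 5.63 in the other 8 animals, 3 of them biallelic. Animals 1, 3 and 4, and also animal 2, are those with 2 libraries. Camera with a preset correlation called the list (adjusted p = 0.0397), and the adjusted p = 0.854 with an estimated correlation. No member passed among 30 imprinted genes (20 lower, median -0.29, H13 -0.63, Gnas -0.45) or 15 reported Plagl1 targets (9 lower, median -0.13, Dcn -1.19). Without wild type animals 7, 8 and 9 the medians of these 2 lists were -0.12 and 0.15, with 9 of the 15 Plagl1 targets higher and Dcn at 0.44. Fry called no list in the chondrocytes (smallest adjusted p = 0.695).

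**Figure D3:**
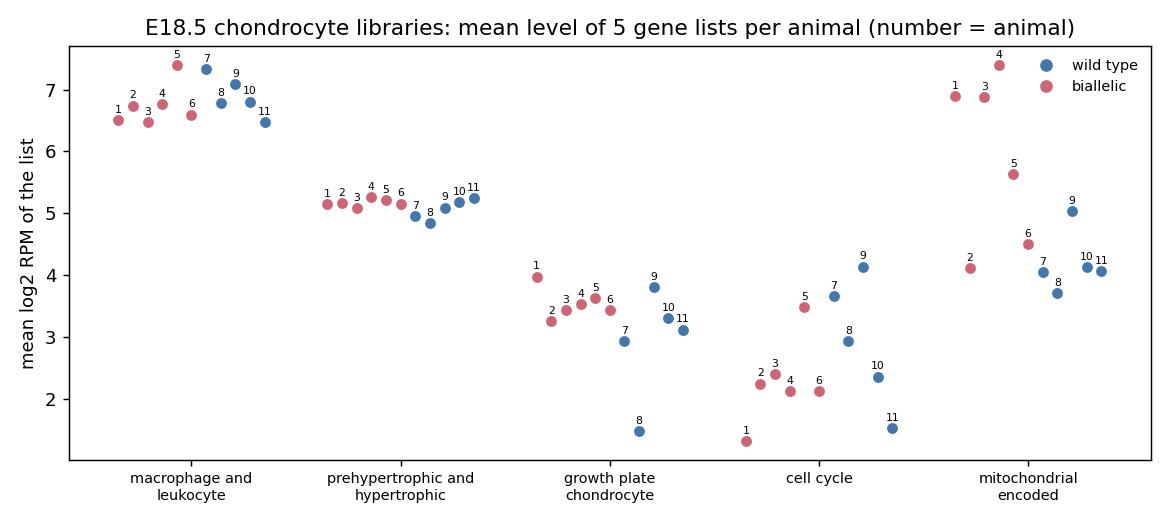
Mean level (log2 RPM) of 5 gene lists in each of the 11 chondrocyte animals, with wild type in blue, biallelic in red and the animal's number above each point. Macrophage and leukocyte genes have the highest or second highest mean in every animal, and the mitochondrial list is highest in biallelic animals 1, 3 and 4.

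Between tables, no gene was called in more than 1 of them. At an unadjusted p under 0.01, E13.5 and P0 shared 5 genes in the same direction: Plagl1, Slc7a10, Ctla4, Gm11808 and Phactr2. The 4 shared higher genes compared with 0.022 expected (one-sided Fisher's exact p = 3.62e-09, with Plagl1 counted). Plagl1 and Slc7a10 were the 2 genes that P20 shared with each of E13.5 and P0, and the chondrocytes shared Plagl1 alone with each tongue stage. Phactr2 was at -0.88 (SE 0.36) and Ltv1 at -0.93 (SE 0.42) in the chondrocytes, neither past the threshold, and Fuca2 was at 0.12 (SE 0.21).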

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

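The tests reported in this part rest on rules fixed before the data were examined, except the choice of lists whose animal means were examined, which followed the results.

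In the chondrocyte animals 72 sets of values (36 measures in each genotype) were examined for 1 animal lying far from the rest of its group, and 7 had one, where chance gives about 1 in 20, or 3.6. Biallelic animal 5 accounted for 4 of them. Its Dcn level was 6.92 log2 RPM against 4.21 to 4.86 in the other biallelic animals, its Mcm6 level 4.91 against 3.29 to 3.72, its perichondrial fibroblast list mean 5.10 against 2.13 to 3.04 and its macrophage and leukocyte list mean 7.40 against 6.47 to 6.77. H13 was at 6.65 in biallelic animal 6 and at 5.74 to 5.96 in the others. Lect1 had 0 reads in wild type animal 8, shown as -2.69, and was at 1.86 to 2.97 in the other wild type animals, so that this animal carries much of the wild type SD of that gene, and without it the log2 fold change was 1.36 in place of 2.37. The mitochondrial transcript mt-Co3 had 1 read in wild type animal 11, the shallowest library, shown as -1.56, and was at 0.34 to 1.05 in the others.

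For 2 of 71 named genes the genotypes separated fully at both E13.5 and P0, in opposite directions. Pax3, a regulator of muscle progenitors, had a log2 fold change of -1.06 at E13.5 and 0.62 at P0, and Fbln5, an elastic fibre protein, -0.48 and 0.20. That separation itself was not tested, and the contrast of the effects at P0 and E13.5 over all genes did not pass the threshold for either gene (limma adjusted p = 0.901 for both).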

How the results depend on the processing

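The averaged tongue effect and its settings, and the run without wild type animals 7, 8 and 9, were chosen after the results were seen. Each count over all genes was recomputed under 16 to 22 alternatives. The count at E13.5 and P20 stayed 0 except with array weights, which gave 667 genes (176 higher, 491 lower) and 1 gene (at P20 the weights did not converge). The chondrocyte count stayed 0 in all 22. For P0 (2 genes) array weights gave 7, median centring 1, quantile normalization 1, and no filter, no trend, a robust trend and voom each gave 0, with 0 to 4 over left-out replicates. The adjusted p of Phactr2 ranged from 0.00188 to 0.484 over these settings, and the cause was not tested. Plagl1 at P0 was 0.99 with median centring (adjusted p = 0.201) and 0.99 with quantile normalization (adjusted p = 0.0551), and 0.99 to 1.10 over left-out replicates, none past the threshold with fewer libraries. Over the alternatives run for it (10 in each tongue table and 15 in the chondrocytes, without voom, array weights or other filters and trends) Plagl1 ranged from 0.96 to 1.36 at E13.5, 1.16 to 1.46 at P20 and 1.17 to 1.99 in the chondrocytes. For P20 minus P0, 1 gene (Phactr2) was called with median centring, 1 with a filter at 5 RPM, and 0 to 1 over left-out replicates. The averaged effect gave 2 genes with a filter at 5 RPM, which tests fewer genes, and 3 to 4 over left-out replicates. Genes shared at an unadjusted p under 0.01 in place of an adjusted 0.05 numbered 5 for E13.5 and P0, 2 for E13.5 and P20, 2 for P0 and P20, and 1 for the chondrocytes with each stage. Of 1421 values of named genes other than Plagl1, 1373 kept direction and side of the threshold, 26 lost and 19 gained a call, and 3 turned, all without animals 7, 8 and 9: Mfap5 (0.45), Prrx1 (0.12) and Dcn (0.44). Camera with an estimated correlation called 0 lists in each table, against 4, 8, 13 and 2.

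Replicate numbers showed no steady pairing of the tongue libraries. Deviations of same-numbered libraries correlated (across genes, which are not independent) at 0.159, 0.042 and 0.137 at E13.5, -0.343, -0.486 and 0.362 at P0 and -0.314, -0.288 and -0.647 at P20. Differently numbered libraries correlated at -0.138 to 0.055 at E13.5, so a weak pairing stays open there. They reached 0.683 at P0 and 0.618 at P20. With the replicate number as a block 0 genes were called at P0. Plagl1 kept its value of 1.03, which a balanced block cannot change (limma adjusted p = 0.509). The block left the counts of 0 at E13.5 and P20 and ended the averaged call of Ctla4 (0.76, adjusted p = 0.554). At E13.5 limma's smallest adjusted p was 0.159 with the block and 0.917 without it.

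A Y-linked covariate was not run in the tongues, whose tables hold 0 such genes, and the alternatives on repeat libraries were not run, since the table holds 1 column per animal. In simulated chondrocyte data, with genes varying independently, 60% of genes changed 4-fold were called, against 93% at P0. Effects of that size were thus less often detected there in the simulation.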

Other observations

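Of the tests in this part, the runs of neighbouring genes and the shift of biallelic replicate 3 were set out before their results were seen. The splits of the libraries, and the tests of scaling and flanking DNA near Plagl1, of genotype, of the neutrophil list and of depth were set out after theirs. The neutrophil tests were first made on differences of means and, after those were seen, put as gaps between animals, with the same verdicts.

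Slc7a10, a transporter of small neutral amino acids found in brain and in white fat cells, was low in the wild type tongue at each stage, at 0.75 ± 0.31, 0.70 ± 0.33 and 0.43 ± 0.06 RPM at E13.5, P0 and P20 (SD, n = 3 each). The biallelic tongues held 2.49 ± 0.33, 1.85 ± 0.44 and 1.99 ± 0.91 RPM (SD, n = 3 each), and every biallelic value exceeded every wild type value of its stage. Permuting genotypes within stages gave an exact two-sided p of 0.00025 for Slc7a10, the smallest possible, chosen after its values were seen. In the chondrocytes it had at most 1 read in any animal.

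The imprinted genes Igf2, Dlk1 and H19, picked after their values were seen, were at lower levels at P20 than at P0, a comparison across separate tables that was not tested. In wild type libraries Igf2 was at 1399.0 ± 98.3 RPM at P0 and 40.9 ± 6.57 RPM at P20, Dlk1 at 227.4 ± 17.5 and 1.68 ± 0.14 RPM, and H19 at 5857.0 ± 658.9 and 526.7 ± 130.7 RPM (SD, n = 3 each). At P20 the biallelic levels were 99.2 ± 58.4 RPM for Igf2 and 953.6 ± 639.1 RPM for H19 (SD, n = 3 each). Biallelic replicate 3 was the highest of the 6 libraries for Igf2 (7.36 log2 RPM), Dlk1 (3.41), Meg3 (7.05) and H19 (10.72). The most abundant chondrocyte transcripts, as means over the 11 animals, were Fth1 (14.53 log2 RPM), Thbs1 (13.88), Ftl1 (13.05) and Arg1 (12.52), and Hmox1 (12.04) and the monocyte gene Cd14 (11.23) were also among the first 20.

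Of the 10 tested genes within 1 Mb of Plagl1, 9 had negative averaged effects in the tongue, and Phactr2 alone passed the threshold. Their mean was -0.26, and 11 of 10710 other runs of 10 neighbouring genes (0.103%) had a mean as low. This argues only weakly against a chance run, since these genes and the averaged effect were chosen after their values were seen. The runs overlap one another, so they are not independent. Without Phactr2 the share was 0.093%. After median centring the mean was -0.253, which argues against library scaling. Its SE of 0.078 was taken over the 10 genes and does not measure the spread between libraries. DNA of another strain kept around the altered locus cannot be told apart from an effect of Plagl1 or of the alteration on its neighbours, because the tables hold no allele counts and the locus goes with genotype, and the genes before Plagl1 (mean -0.052) and after it (-0.354) differ in size without deciding this.

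The hypoxia and glycolysis list was high in E13.5 biallelic replicate 3 alone, 4.74-fold above the wild type mean (2.24 on the log2 scale). Genotype acting alike in every library is argued against by the values that show the pattern, since the mean of biallelic replicates 1 and 2 differed from the wild type mean by 0.007 (wild type SD 0.047). Library scaling is argued against by the median of all other genes, shifted by 0.003. A delay or low oxygen during collection of that embryo may be one source and a difference in its stage another, and no value in the tables tests either.

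Several neutrophil genes had lower means in the biallelic chondrocytes, S100a8 (-1.82) and Cxcr2 (-2.83) among them. RNA of granulocytes in wild type animals 7, 8 and 9 is a candidate source. A list of 30 other neutrophil genes, 22 of them tested, 12 with lower biallelic means and 0 held by another list, had a mean at least 0.994 higher in each of these 3 animals than in any of the other 8, in cells gated on Cd24a and Cd200. Granule genes carried it, with Mpo at 7.26, 5.58 and 8.12, Ngp at 8.07, 6.89 and 7.16 and Ltf at 5.76, 6.42 and 5.35 log2 RPM. They were not confined to these animals, since biallelic animal 5 held Mpo at 5.46, Elane at 4.76 (4.85 in animal 8) and Ngp at 4.10, and wild type animal 10 held Mpo at 3.61. The most abundant members, Clec4d, Mmp8 and Itgam (means of 10.18, 9.58 and 8.85), which other myeloid cells also express, were not higher in animals 7, 8 and 9. Genotype acting alike in every animal is argued against by wild type animals 10 and 11, the higher of which lay at -1.06 from the lowest of the 3 (biallelic SD 0.472), and depth by the 3 other animals of like depth (7221013 to 8790675 reads), which lay at least 1.018 lower. Both values are part of the gap above, in animals picked because they stood apart, so they add no separate evidence, and an effect of genotype that reaches some animals only stays open.

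Other divisions of the same libraries were counted for each result. For the averaged tongue effect (4 genes), 2 of 100 divisions drawn gave as many, the real one included, a share under 0.05. This is weak support and does not exclude chance, since 100 of 4000 were drawn and the contrast was added after the data were examined. Plagl1, whose expression defines the groups, is also among the 4 genes. The highest other gave 27, and what that division separates was not tested. At P0 the real division gave 2 genes and the highest other 0, with 1 of 10 divisions as large, and 10 divisions are too few to give a share under 0.05. With 0 genes called any division is as large, so the remaining counts do not test chance. They were 10 of 10 divisions at E13.5 (0 genes, highest other 0) and 10 of 10 at P20 (0 genes), which are also too few to give a share under 0.05. At P20 wild type 1 and 2 with biallelic 3 against the rest gave 101, which points to a structure other than genotype. In the chondrocytes (0 genes) they were 100 of 100 divisions drawn, and 286 genes separated biallelic 5 and 6 and wild type 7, 8, 9 and 10 from the rest. For each contrast between stages (0 genes) they were also 100 of 100, with the highest at 369 for P0 minus E13.5, 2 for P20 minus P0 and 329 for P20 minus E13.5.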
